A study of Axonopus compressus with 6 samples.

How the data were processed

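RNA-seq was performed on roots of Axonopus compressus (carpetgrass, a warm-season turf grass) of 1 accession, A58. Seedlings whose roots were about 5 cm long received no added aluminium or 100 μM aluminium for 24 h, and the roots were harvested. There were 3 control libraries and 3 aluminium libraries. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made by standard Illumina protocols. Bowtie2 version 2.2.3 is named in the submitters' processing notes, without a stated role. The row identifiers have the form that the Trinity assembler gives to its gene-level features, in which the numbers after DN and c together name a component, that is, a read cluster that the assembler resolves into genes. Features with the same DN number alone are called a DN group here. The assembler's version, the counting tool and any filter are not given in the sources used here. No genome or gene annotation was used here, and the deposited table pairs its identifiers with no gene names, functions or positions. The gene lists fixed before the data were examined could therefore not be matched or tested, and features are described by abundance, length and assembly component instead.

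The authors deposited 1 table of RPKM values (reads scaled by feature length and by library total), per the file name, with 108674 features in rows and the 6 libraries in columns. No feature was 0 in every library. RPKM corrects for library total and feature length but not for composition, so a rise in some features lowers the RPKM of the others.

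The RPKM values kept enough digits for the reads to be worked back. In features under 1 RPKM the most frequent ratio of 2 libraries, that of equal read numbers, gave the relative depth. The steps between the values of 1 read in features of different length then gave the library totals, and each feature got the smallest whole length that made its reads whole. With these, 100.0% of features came out as whole reads in the 6 libraries within a tolerance of 1e-06 reads. A minimum length of 201 bases was set. The 2169 features whose smallest whole length was shorter were scaled up to its first multiple at or above this minimum. Where all 6 read numbers and the length share a factor that leaves the length above this minimum, the true number is a multiple of the recovered one. On simulated Poisson reads with the same means and lengths (108642 features), 99.5% of features were recovered exactly, 0.49% were recovered as a smaller multiple, and 99.5% of the reads were recovered. The recovered reads of the real libraries made up 99.5% of the library totals. The library totals ranged from 32544238 to 35204519 reads. Whether a read or a read pair was counted once is not given in the sources used here, and the word read is used for the unit counted. Reads are not known to be independent molecules, so limits from them cover no more than counting error.

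The main test was chosen before the data were examined, for a table that gives only RPKM. Features with at least 1 RPKM in at least 3 libraries were kept (50679 features), and log2(RPKM + 0.5) was compared between the 2 groups with limma version 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change on this scale understates the change of weakly expressed features. Because the file holds RPKM and not counts, a count model was not used; limma's voom on the recovered reads was run as an added alternative. The test was tried on simulated negative binomial reads (47328 features kept, dispersion 0.0050). It found 62 of 66 features changed by 4-fold, 49 of 67 changed by 2-fold and 24 of 67 changed by 1.5-fold, and 2.17% of its calls were false. The simulated spread was that of the control libraries alone. No other features were changed, a far smaller share than was called in the data, so these rates may differ there.

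Values of single libraries were compared between groups with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3. Pairs of libraries were compared by correlation and by a chi-square of their recovered reads in features with at least 20 reads in the pair, and no 2 libraries agreed within sampling noise, so each counted as 1 replicate. The labels do not say that libraries of a group came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. Control and aluminium libraries share replicate numbers, and the labels do not say that a number marks a shared batch.

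The rule for named features, fixed before the data were examined for a table without annotation, was the 2 largest rises and the 2 largest falls among features past the test, with a mean of at least 5 RPKM in the higher group and no overlap between the groups. The abundance classes, assembly components and features read in only 1 group were chosen after the data were seen. Alternatives changed the pseudocount (0.1 and 1), the filter (none, or 5 RPKM), the scaling (median of ratios, quantile), the variance model and the replicate block, and left out each library in turn. The alternatives added after the data were seen were voom, reads thinned to 1 depth, leaving out the most abundant DN group, and components defined by the DN number alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.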

Results

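Transcript levels were measured in roots of carpetgrass accession A58 after 24 h without added aluminium or with 100 μM aluminium, an ion that is toxic to roots in acid soils. The series has 3 control and 3 aluminium libraries. The deposited table gives RPKM for 108674 assembled features, each a gene-level group of contigs, with a median length of 481 bases (25th to 75th percentile 288 to 1015, longest 15032). The library totals worked back from the RPKM values were 32894752, 33216298 and 32544238 reads in control libraries 1, 2 and 3, and 33576684, 35204519 and 34507039 reads in aluminium libraries 1, 2 and 3. The features carry no gene names or genomic positions in the table, so they are reported by identifier, abundance, length and assembly component.

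The comparison of treated with untreated roots addressed the response of root transcripts to aluminium. Under the rule for named features, the 2 largest rises and the 2 largest falls were taken. TRINITY_DN21461_c3_g1, a feature of 1019 bases, was at 2.62 ± 0.56 RPKM in control and 25.3 ± 0.92 RPKM in aluminium libraries (SD, n = 3 each), from 73 to 110 and 839 to 944 reads per library. Its log2 fold change was 3.06 (SE 0.13, limma adjusted p = 5.72e-06). TRINITY_DN45556_c0_g1, of 723 bases, rose from 0.98 ± 0.28 to 9.23 ± 1.22 RPKM, a log2 fold change of 2.72 (SE 0.18, limma adjusted p = 2.73e-05) from 16 to 28 and 211 to 265 reads. TRINITY_DN33249_c0_g3, of 755 bases, fell from 11.6 ± 1.53 to 0.80 ± 0.05 RPKM, with a log2 fold change of -3.21 (SE 0.14, limma adjusted p = 6.21e-06). It had 252 to 329 reads in control and 20 to 22 in aluminium libraries. TRINITY_DN30924_c0_g3, of 1120 bases, fell from 15.5 ± 3.22 to 2.48 ± 0.21 RPKM, with a log2 fold change of -2.41 (SE 0.15, limma adjusted p = 2.05e-05) and 471 to 692 against 87 to 107 reads. As ratios of mean RPKM, the rises were 9.64-fold and 9.39-fold, and the falls were 14.5-fold and 6.24-fold. As the rule required, in each of these 4 features all 3 aluminium libraries lay on the same side of all 3 control libraries. What these features encode is not known here, because the table gives no annotation.

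**Figure D1:**
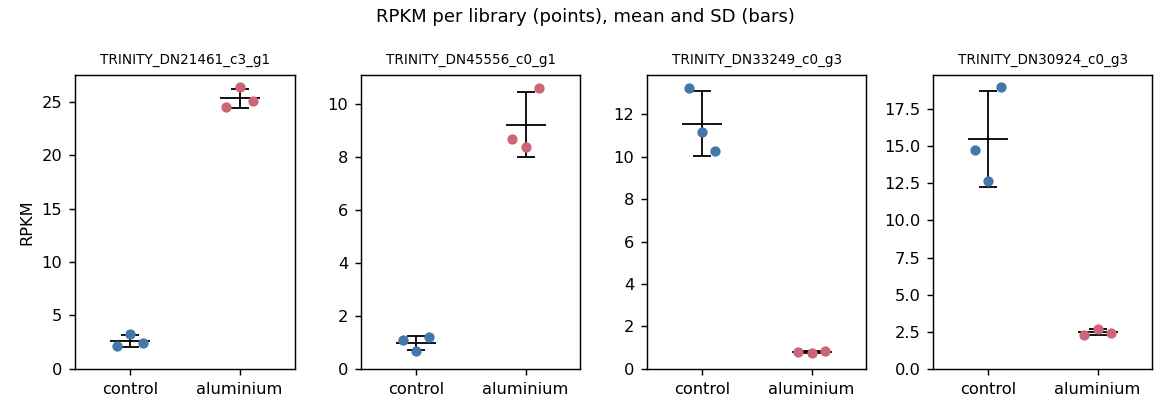
RPKM of the 4 named features in control and aluminium libraries, with 1 point per library and bars for the mean and SD of 3 libraries. The aluminium libraries of TRINITY_DN21461_c3_g1 and TRINITY_DN45556_c0_g1 lie above all control libraries (means 25.3 against 2.62 and 9.23 against 0.98 RPKM), and those of TRINITY_DN33249_c0_g3 and TRINITY_DN30924_c0_g3 lie below them. The rule for named features required that the groups do not overlap.

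Of the 50679 features tested, 17939 (35.4%) differed between the groups at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 9159 were higher and 8780 lower in aluminium-treated roots. Most changes were small. The median change of these features was 1.47-fold (25th to 75th percentile 1.31 to 1.71), with a median standard error of 0.10 on the log2 scale, and 88.4% of them changed by less than 2-fold. Of the 2073 features that changed by at least 2-fold, 1564 rose and 509 fell, so that 75.4% were rises, while quantile normalization gave 1301 rises and 657 falls (66.4% rises). The 2-fold counts differed between settings, with 2319 rises and 815 falls at a pseudocount of 0.1, 912 and 289 at a pseudocount of 1, 2469 and 932 with voom on the recovered reads, and 672 and 220 with a filter of 5 RPKM. On the pseudocount scale of the main test, 34 features rose and 5 fell by at least 4-fold. This scale understates the change of weakly expressed features, so these are not counts of 4-fold ratios of mean RPKM. The median change and the 2-fold counts of the main test are on this scale too. The groups did not overlap in 49.2% of the tested features, against 10% given by chance for 3 libraries against 3. The median log2 change of all tested features was 0.01. The near-even balance of the 9159 rises and 8780 falls turned to 8490 rises and 9346 falls with quantile normalization.

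**Figure D2:**
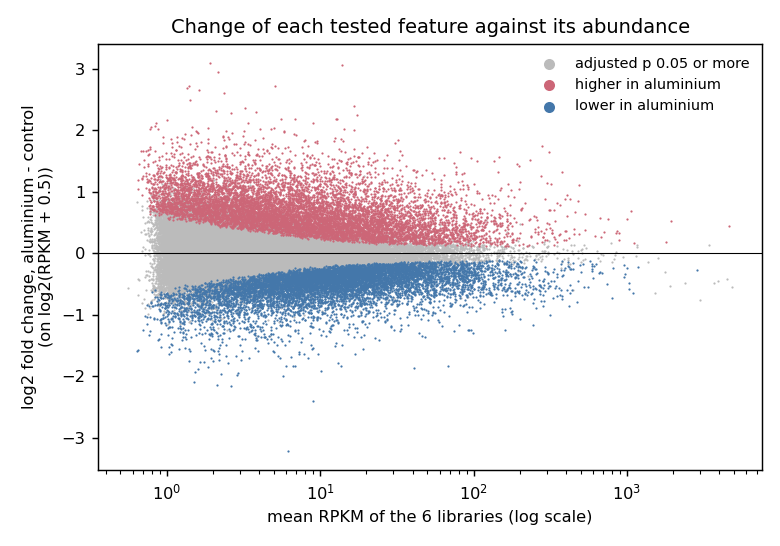
Log2 fold change (aluminium minus control, on log2(RPKM + 0.5)) of each tested feature against its mean RPKM over the 6 libraries on a log scale, with 1 point per feature and the features past the test in colour. Features that rose by at least 2-fold (1564) outnumber those that fell by as much (509).

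The features that rose under aluminium held 21.6 ± 0.17% of the reads in control libraries and 30.7 ± 0.17% in aluminium libraries (mean ± SD, n = 3 each). The features that fell held 34.7 ± 0.50% and 26.3 ± 0.36% (SD, n = 3 each). These sets were chosen by their change, so the shares describe its extent and are not a test of it. Among the 100 most abundant features, the lowest of which had a mean of 428 RPKM, 24 rose, 34 fell and 42 did not pass the test, and 1 of the changed features moved by at least 2-fold.

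The direction of change varied with abundance. Of the 13442 tested features with a mean under 2 RPKM, 1496 (11.1%) rose and 578 (4.30%) fell, and of the 13996 features from 2 to 5 RPKM, 2161 rose and 1400 fell. From 5 to 10 RPKM, 1741 features rose and 1829 fell. Of the 11863 features from 10 to 50 RPKM, 2965 rose and 3850 fell, and of the 2711 features of 50 RPKM or more, 796 (29.4%) rose and 1123 (41.4%) fell. The median log2 change went from 0.08 under 2 RPKM to -0.07 at 50 RPKM or more. On the pseudocount scale of the main test, rises of at least 2-fold outnumbered falls in every class. They numbered 537 against 158 under 2 RPKM and 52 against 17 at 50 RPKM or more. Quantile normalization brought the numbers closer, to 1089 rises and 850 falls under 2 RPKM and to 867 rises and 1059 falls at 50 RPKM or more.

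In its share of reads from weakly expressed features, aluminium library 2 lay within the range of the controls. Features under 2 RPKM, tested or not, held 2.75, 2.87 and 2.80% of reads in control libraries 1 to 3, and 3.26, 2.86 and 3.24% in aluminium libraries 1 to 3 (two-sided exact permutation p = 0.2). Without aluminium library 1 or 3, the rises under 2 RPKM numbered 789 and 900, and without aluminium library 2 there were 1363. Without control libraries 1, 2 and 3 they numbered 1053, 1068 and 1075, so leaving out a control library lowered them too. The falls under 2 RPKM numbered 381, 499 and 424 without aluminium libraries 1, 2 and 3, and 311, 300 and 320 without control libraries 1, 2 and 3.

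**Figure D3:**
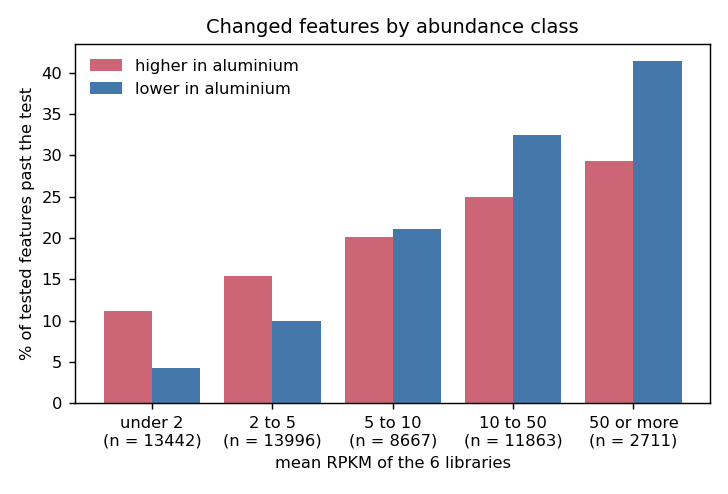
Share of tested features past the test (limma, adjusted p under 0.05), in percent, by class of mean RPKM, with 1 bar for features higher and 1 for features lower in aluminium. Rises exceed falls under 2 RPKM (11.1 against 4.30%), and falls exceed rises at 50 RPKM or more (41.4 against 29.4%).

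Features of the same assembly component mostly changed in the same direction, but many components were split. The tested features fell into 30019 components. In 2956 of them at least 2 features changed. All changed features rose in 1139 of these, all fell in 806, and features changed both ways in 1011. With directions shuffled among the same changed features, 1621 components on average were split (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). The shuffle treats features as independent, so it does not allow for library noise shared within a component. Within groups, pairs in components changed 1 way had a mean correlation of 0.090, against 0.020 for like-directed pairs from different components. In 14 components at least 5 features changed and all rose, and in 5 at least 5 changed and all fell. Without control library 1, control library 2 and aluminium library 1, the components changed both ways numbered 598, 586 and 593. The components with at least 2 changed features also fell in these fits, to 2064, 2039 and 2044.

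Some features were read in 1 group only. In the aluminium group 57 features had at least 30 reads in total and none in any control library, and in the control group 14 features showed the reverse. From counting error alone, a count of 0 allows up to 3 reads over the group's libraries (95% limit). With its reads taken as exact, a feature with 30 reads in aluminium libraries only would then be at least 9.55-fold higher there. The one with the most, 315 reads, would be at least 100.3-fold higher. These limits leave out the counting error of the aluminium reads and the spread between libraries, and the features were chosen for their count of 0. The median length of the 57 features was 450 bases, against 481 for all features. Of the 57, 8 passed both the abundance filter and the test (limma). In 18 of the 57 the highest and lowest aluminium libraries differed at least 5 times in reads per library total. The 18 other ways of taking 3 of the 6 libraries gave 0 to 12 such features. Counting features with any read in all 3 libraries of 1 group and none in the other, 912 were in aluminium libraries only and 267 in control libraries only, and the other 18 sets gave 174 to 464.

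More features were detected in aluminium libraries. At least 1 read was found for 95797, 96891 and 96102 features in control libraries 1 to 3 and for 100082, 97703 and 100110 in aluminium libraries 1 to 3. The groups did not overlap (exact permutation p = 0.1, the smallest possible). Each aluminium library was deeper than each control library. With reads thinned to 1 depth, the numbers were 95730, 96781 and 96102 in control and 99923, 97188 and 99774 in aluminium libraries (exact permutation p = 0.1). At 1 RPKM or more, 49393 ± 533 features were detected in control and 51541 ± 1699 in aluminium libraries (SD, n = 3 each) (two-sided exact permutation p = 0.3), and aluminium library 2, with 49584, lay within the range of the controls. Features of 2000 bases or more held 40.5 ± 0.46% of reads in control and 41.9 ± 0.72% in aluminium libraries (SD, n = 3 each), with an exact permutation p of 0.1, the smallest that this design allows.

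A group of 22 features with the same DN number, from 9 components, held the most reads of all such groups, and its share varied within both groups. It took 1.69, 1.39 and 3.08% of reads in control libraries 1 to 3 and 1.14, 2.06 and 1.17% in aluminium libraries 1 to 3 (exact permutation p = 0.5). Its 10 features of 50 RPKM or more had log2 fold changes of -0.77 to -0.10 and a lowest limma adjusted p of 0.18. Of its 14 tested features 1 passed the test, a weaker one that was higher in aluminium (9.03 ± 2.11 RPKM in control and 17.1 ± 2.0 in aluminium libraries, SD, n = 3 each). Its log2 fold change was 0.90 (SE 0.15, limma adjusted p = 0.0022). The mean share of reads differed between aluminium and control libraries by -0.60 percentage points, less than the SD of the control libraries, 0.90.

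The libraries separated by treatment. Over the 50679 features tested, Pearson's r of log2(RPKM + 0.5) was 0.970 to 0.980 between libraries of the same group and 0.942 to 0.949 between control and aluminium libraries, and Spearman's rho was 0.954 to 0.969 and 0.919 to 0.927. These correlations are across features, which are not independent replicates. The first principal component held 56.1% of the variance and separated the groups, with scores of -54.4 to -51.5 in control and 49.4 to 58.0 in aluminium libraries. The second held 16.2% and set aluminium library 2 (54.9) apart from aluminium libraries 1 and 3 (-23.2 and -28.6). The median chi-square between 2 libraries was 2.84 to 4.38 times its value under counting noise within groups and 9.42 to 10.6 times between groups.

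**Figure D4:**
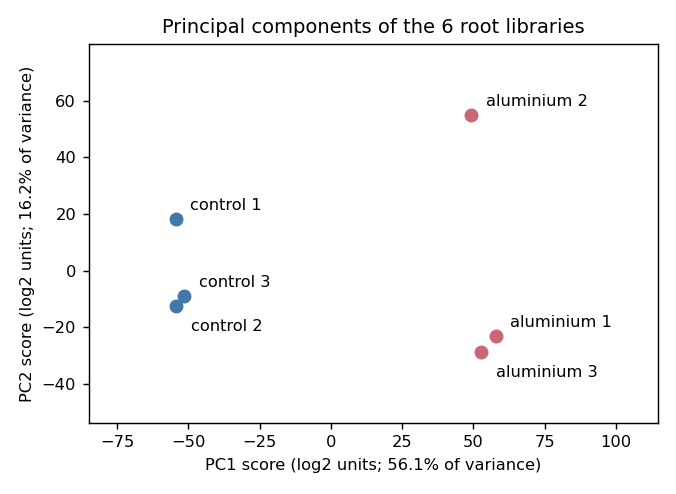
Scores of the 6 libraries on the first 2 principal components of log2(RPKM + 0.5) over the tested features, in log2 units, with 1 point per library. Control and aluminium libraries sit on opposite sides of PC1 (56.1% of variance), and aluminium library 2 lies apart on PC2 (16.2%).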

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

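Voom on recovered reads, thinned reads, leaving out the most abundant DN group and components by DN number alone were chosen after the data were seen. The count of changed features ranged from 13712 to 18964 over the other fits, and no feature called in both the main and another fit changed direction. Leaving out 1 library gave 13807 to 17343 changed features, and 300 to 499 falls and 789 to 1363 rises under 2 RPKM. It gave 586 to 992 components changed both ways, among 2039 to 2875 with at least 2 changed features. There were 1504 components changed both ways among 3760 when the DN number alone defines a component. Requiring a 2-fold change as well left 2073. Of the 2-fold changes, there were 815 falls with a pseudocount of 0.1 and 912 rises and 289 falls with 1, as a larger pseudocount shrinks fold changes. With voom on recovered reads there were 2469 rises and 932 falls, and the cause was not tested. With a filter of 5 RPKM, which tests fewer features (24006), there were 672 rises and 220 falls of at least 2-fold. The lowest correlation within groups exceeded the highest between groups by 0.022; this gap was 0.0083 with no filter and 0.046 with the 5 RPKM filter, and the cause was not tested. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.15, -0.11 and -0.02, and no library matched its own number best). With the replicate block, 14753 features changed and falls under 2 RPKM numbered 372. In this balanced design the block left log2 changes as in the main fit, such as 3.06 for TRINITY_DN21461_c3_g1. The counts thus fell through the variance estimate and the residual degrees of freedom, which were not tested apart. The log2 changes of the 4 named features kept direction and call in all 18 fits, with adjusted p (limma) of at most 0.0017. The gene-list alternatives were not run, because the table pairs no IDs with names, nor was the count-model alternative, planned only for a table of counts; under the 5 RPKM filter no feature under 2 RPKM has a value. In simulated reads with the depth and library number of this series and the spread of its control libraries, 35.8% of 1.5-fold changes were found. A far smaller share of features was changed there than was called in the data, and the share found depends on this. Other depths and other shares of changed features were not simulated.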

Other observations

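Of the tests reported here, quantile normalization was chosen before the data were examined, though the abundance classes were chosen after they were seen. The other tests here were chosen after the results they bear on were seen, except that of depth for features read only in aluminium libraries. A few features stood far higher in 1 library than in the others. In control library 2, 15 features with at least 30 reads lay more than 5 times above every other library and together held 1718 reads. There were 9 such features in aluminium library 1, 4 in aluminium library 3, 1 in control library 3, and 0 in control library 1 and in aluminium library 2. Aluminium libraries 1 and 3 shared weakly read features with single controls: 464 features were read in both and in control library 2, 437 in both and in control library 3, and 346 in both and in control library 1, with no read in the remaining libraries.

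The labels give no batch, day or plant for any library, so a difference in handling between the 2 groups and aluminium treatment cannot be told apart. The real split of the 6 libraries changed 17939 features, 2073 of them by at least 2-fold, and the highest of the 9 other splits into 3 and 3 changed 0 and 0 (limma; up to 1654 at an unadjusted p under 0.05). Each other split mixes control and aluminium libraries, so a group difference adds to its residual spread and lowers its count. Counts of 0 there are thus no reference for data without a group difference. The real split was 1 of 10, and with 10 splits the share cannot fall under 0.05.

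Weakly expressed features rose more often than they fell, by 2.59 to 1 under 2 RPKM. Thinning the reads to 1 depth left 2.64 to 1, and leaving out the most abundant DN group left 2.47 to 1, which argues against depth and against that group as the whole cause. For the class as a whole, a candidate explanation is extra low-level reads in aluminium libraries 1 and 3. Their medians lay 0.15 and 0.13 above the control mean (log2). That of aluminium library 2, 0.019, lay below the 0.038 of the highest control library against the other controls. Quantile normalization left 1089 rises and 850 falls. By construction it removes a shift of a whole class, whether in single libraries or shared by the aluminium libraries, so it does not tell these apart. Between 1167 and 1326 features rose in aluminium libraries 1 and 3 against 2 of the controls, chosen without aluminium library 2. Against the control left out, their median change in aluminium library 2 was 0.53 to 0.62 (log2). This was 58.3 to 63.5% of their change in libraries 1 and 3. The choice can overstate the change in libraries 1 and 3 and so lower this percentage. Over all features of the class, the median change of aluminium library 2 was 0.0042 to 0.041 (log2). Reads confined to libraries 1 and 3 thus do not account for the whole of these rises. A response to aluminium stays open for these features and was not tested apart from the group difference.

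The 57 features read in aluminium libraries and in no control library may have a source other than the roots' own response. Depth is argued against, since thinned reads still gave 3.57 such features for each one in control libraries only (4.07 before thinning). A single foreign source would keep 1 ratio over the 3 libraries; at the ratio that fits the set best, the median chi-square per degree of freedom was 2.87, above the 1.22 to 2.53 (central 95%) of 1000 random sets with like read totals, each at its own best ratio. This form of the test was the last of 3: against a split by depth, computed first, the value was 2.93 and within the 1.39 to 2.98 of random sets, and against the set's pooled split, computed next, it was 4.36, above 1.38 to 2.93, so the evidence against a single source depends on the form and is weak. Several sources, and induction by aluminium, stay open without sequences or annotation.

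In 1011 components some features rose and others fell, which could come from reads moving at random between near-identical features. Such moves would lower the correlation of opposite-moving features within groups. It was 0.041, above that of opposite-moving pairs from different components by 0.049 (95% bootstrap interval 0.018 to 0.080) but below the 0.090 (SE 0.011) of pairs in components changed 1 way. Less the value of like-directed pairs from different components, the latter was 0.069, and the difference between the 2 excesses was -0.020 (95% bootstrap interval -0.059 to 0.019), so the excess of 0.049, set against different components, does not exclude shared reads, which a positive correlation common to features of 1 component can hide. Shared reads and separate regulation of the features of 1 component both stay open, and whether such features are gene copies is not known here.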
